A study of Mus musculus and Homo sapiens
Mus musculus with 4 samples.

How the data were processed

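The data are 4 arrays of lung RNA from BALB/cJ mice, 2 for sensitized mice and 2 for mice that were sensitized and challenged. Per the labels' protocols, total RNA was isolated with RNeasy columns, 20 µg were reverse transcribed for each labelling, and the cDNA was labelled indirectly with Cy3 or Cy5. The reference cDNA on each array was a pool from 6 control animals, per the labels' protocols, and the labels of its channel name particle-free air and the treatment of the group. A group's control is therefore 1 pooled sample, the pools of the 2 groups differ, and the spread between control mice is not measured. In both groups array 1 carried the UCP sample in Cy5 and array 2 carried it in Cy3, per the labels. Which mice supplied the UCP RNA of each array is not given in the sources used here.

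The deposited values are log2 ratios of the 2 channels, 1 per probe and array. The file does not state the base, which was read from the values: the dimmest spots repeat values that lie on log2 ratios of small whole numbers plus 1 constant per array. These constants were 0.45, 0.60, -0.21 and 0.41, so the deposited ratios carry 1 scaling factor per array. The image analysis, background correction, normalization method and filters are not given in the sources used here. A ratio of 0 had been stored as 1e-05 before the logarithm, which gave the values -16.16, 17.21, -16.82 and 17.02 on 121, 45, 149 and 24 spots. These lie at the bottom of array 1 and at the top of array 2 of each group, so the deposited array 2 carries the opposite sign of its channel ratio and both arrays of a group point in the same direction. That this direction is UCP over particle-free air is likely but not stated, and with the opposite direction every sign in the report would turn.

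A rule written before the data were examined also decided the sign: the arrays of a group were to be used as deposited if they correlated above 0 in both groups. Over the 17332 probes with a value on all 4 arrays the Pearson correlation was 0.0028 in sensitized and 0.0227 in challenged lungs, and the rank correlation was 0.0900 and 0.0988, so the values were used as deposited. These correlations lie close to 0, and with each pair's own probes the Pearson correlation fell just below 0 in both groups, so the rule alone would decide little, and turning array 2 was run as an alternative. The arrays had medians of 0.122, -0.067, 0.055 and -0.036 and interquartile ranges of 1.36, 0.839, 0.536 and 0.563. Missing values made up 7.07%, 5.37%, 4.79% and 2.75% of the arrays. Spots on ratios of whole numbers up to 10, taken as low signal, made up 13.0%, 8.38%, 7.04% and 6.61%, where 2.92%, 3.04%, 3.48% and 3.23% would fall on such values by chance.

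Of 20205 probes, 13852 carried 1 gene symbol, 0 carried several and 6353 carried none. Gene symbols were those of the platform table, and for 13849 probes the Entrez number was found in the RefSeq gene table of GRCm38.p6 with the identical symbol. Tests used the 17332 probes with a value on all 4 arrays, of which 11972 were named. No further normalization or centring was applied. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated t-tests on 2 residual degrees of freedom. The 3 comparisons were each group's mean against 0 and the difference of the 2 means. Benjamini-Hochberg adjusted p-values were taken over all probes tested, with a threshold of 0.05. Since the dyes are swapped within each group, a dye effect cancels in the group mean.

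Before the data were examined, 34 gene lists were written for lung cell types, inflammation, oxidative and xenobiotic stress, metabolism and tissues that lie near the lung. Probes were averaged per gene, and each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. All 34 lists were large enough. A list is said to rise or fall on this test. Camera was also run with the correlation estimated from the arrays, and no list passed in that form. A rotation test, fry, passed 17 lists in sensitized lungs, 2 in challenged lungs and 13 for the difference. The percentile of each list's median was taken among 10000 random lists of the same size. The number of a list's genes past the threshold is given over all genes tested and also adjusted over the list alone. Concordance of the dye swap was counted at 1.5-fold and tested with an exact binomial test, with 2-fold and 1.25-fold as alternatives, and its confidence intervals are exact.

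The rule for naming genes was fixed before the data were examined. In each group the 10 probes per direction that passed were to be named, filled up where too few passed by a ranking on the smaller of the 2 array values among probes with the same sign on both arrays. None passed, so all of these genes come from the ranking. For the difference, 5 per direction were ranked by the gap between the arrays of the 2 groups. Up to 4 members with the largest mean were allowed per described list, and 20 genes of allergy, oxidative stress and airway secretion were to be named whatever their values. Genes with a stored ratio of 0 are given by the value of the other array. Among the 20 genes ranked in sensitized lungs, 10 had a low-signal value (50.0%, against 17.6% of all probes), and in challenged lungs 5 of 20 did (25.0%, against 11.5%).

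The scripts were tested on simulated data with added changes. Of 50 probes each with an added log2 change of 1, 2, 4 and 8 in the sensitized group, 0%, 4.00%, 88.0% and 98.0% were recovered, with 8 false calls among 17332 probes. Of 30 simulated lists of 20 genes, all 10 that were moved by 0.5 were called at the preset correlation, 0 of the others were, and 0 were called with an estimated correlation. The test therefore had little power for single genes with a change of log2 2 or less, and sizes between 2 and 4 were not simulated. Both simulated groups had the same spread, and many changes were added at once, which eases the adjusted threshold. The recovery at log2 4 and 8 therefore need not hold for the sensitized arrays, which spread more widely. With an estimated correlation, power was also low for lists with a shift of 0.5. The simulated genes varied independently of each other, so the list counts cannot show whether a preset correlation of 0.01 suits real lists. Larger list shifts were not simulated. Alternatives fixed in advance were a block for the array number, centring and scaling of the arrays, keeping probes with missing values, turning array 2, fitting each group's arrays alone, a robust prior, 1 mean per gene, other sizes for concordance, camera with an estimated correlation, and leaving out each array in turn. Leaving out probes with stored ratios of 0, leaving out probes with a low-signal value, and testing the lists on centred and scaled arrays were added after the data had been seen. Lists of thymus and liver genes, used beside 2 lists of the report and in the closing section, were written after the values of several of their genes had been seen.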

Results

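Lung RNA of BALB/cJ mice that breathed air with UCP, a particle exposure whose abbreviation the labels leave unexplained, was compared with lung RNA of mice that breathed particle-free air. One group of mice had been sensitized to ovalbumin (OVA), an egg protein used as a model allergen, and the other had been sensitized and then challenged with it. Per the labels, the mice came in groups of 6 and each group was measured on 2 cDNA arrays with 2 dyes each and the dyes swapped between them, so n = 2 arrays in each group. On every array the UCP sample was set against cDNA pooled from 6 control animals. The sensitized arrays held values for 18777 and 19121 of 20205 probes, and the challenged arrays for 19237 and 19650. All 4 arrays had a value for 17332 probes, and these covered 8845 named genes. The middle 50% of the log2 ratios spanned 1.36 and 0.84 on the sensitized arrays and 0.54 and 0.56 on the challenged arrays. The 2 arrays of a group ranked the probes with a correlation of 0.0900 in sensitized lungs and 0.0988 in challenged lungs. Ratios are given as UCP over particle-free air, which is the likely direction but is not stated in the sources used here. The number of arrays limits the precision, and the labels do not say whether the 2 arrays of a group held RNA of different mice, so each error is the spread between arrays.

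The first comparison asked how UCP changed gene expression in sensitized lungs that had not been challenged. Genes of the alveolar lining were lower after UCP, and markers of heart and skeletal muscle were higher. All 10 measured genes of the alveolar type 2 and surfactant list were below 0 on both arrays, and the list fell, with a median log2 ratio of -0.80 (adjusted p = 6.31e-06, and adjusted p = 0.360 with an estimated correlation). Sftpb, a surfactant protein needed for breathing, had a mean log2 ratio of -1.51 ± 0.11 (SD, n = 2 arrays). Sftpc, a surfactant protein made only by type 2 cells, had -1.17 ± 0.58, the desaturase gene Scd1 had -1.12 ± 0.23 and Lpcat1, an enzyme of surfactant lipid synthesis, had -0.95 ± 0.25. Of these 10 genes, 7 passed when adjusted over the list alone and 0 passed over all genes tested. All 8 alveolar type 1 markers were also below 0 on both arrays, and the list fell, with a median of -0.77 (adjusted p = 0.000603, and adjusted p = 0.360 with an estimated correlation). Among them, Krt7 had -1.44 ± 0.56 and the water channel gene Aqp5 had -0.85 ± 0.58. The list of club cell and secretory airway markers fell, with a median of -0.60 and 7 of 9 genes below 0 on both arrays (adjusted p = 0.0235, and adjusted p = 0.360 with an estimated correlation). Haptoglobin, Hp, had -0.79 ± 0.10 and Scgb3a1, a secretory protein of the airways, had -0.60 ± 0.24. The cardiac and skeletal muscle list rose, with a median of 0.39, 12 of 23 genes above 0 and 3 below 0 on both arrays (adjusted p = 0.000403, and adjusted p = 0.360 with an estimated correlation). Pln, a regulator of the heart's calcium pump, had 1.94 ± 0.23, the heart myosin-binding gene Mybpc3 had 1.60 ± 0.77, and Tnnt3 of fast skeletal muscle had -1.69 ± 2.10. In the muscle list 2 genes passed when adjusted over the list alone, and in the type 1 and club cell lists 0 did. A list of thymus genes, written after the values of several of them had been seen, also rose in these lungs, with a median of 0.20 (adjusted p = 0.0216, and adjusted p = 0.3002 with an estimated correlation).

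Antioxidant, macrophage and antigen presentation genes were lower in the same lungs. The NRF2 and antioxidant response list fell, with a median of -0.61 and 14 of 19 genes below 0 on both arrays (adjusted p = 0.00195, and adjusted p = 0.360 with an estimated correlation). Gclc, which encodes the catalytic part of the enzyme that limits glutathione synthesis, had -1.25 ± 0.28, the ferritin gene Ftl1 had -1.14 ± 0.65, and the peroxiredoxin gene Prdx1 had -0.96 ± 0.00. The superoxide, peroxide and thiol enzymes fell, with a median of -0.53 and 8 of 11 below 0 on both arrays (adjusted p = 0.00861, and adjusted p = 0.360 with an estimated correlation), including Sod1 at -0.91 ± 0.01 and catalase, Cat, at -0.88 ± 0.60. The macrophage markers fell, with a median of -0.52 and 9 of 13 below 0 on both arrays (adjusted p = 0.00664, and adjusted p = 0.360 with an estimated correlation), and the proteases Ctsk and Ctsd had -1.55 ± 0.29 and -0.93 ± 0.16. Antigen presentation genes fell, with a median of -0.72 and 10 of 13 below 0 on both arrays (adjusted p = 0.000804, and adjusted p = 0.401 with an estimated correlation). In that list the immunoproteasome subunit Psmb9 had -0.95 ± 0.15 and the class II gene H2-Eb1 had -0.91 ± 0.39.

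The largest list was that of the cytosolic ribosomal proteins, which fell, with a median of -0.51 and 43 of 55 genes below 0 and 1 above 0 on both arrays (adjusted p = 1.01e-08, and adjusted p = 0.360 with an estimated correlation). Examples were Rpsa at -1.13 ± 0.42 and Rplp0 at -0.99 ± 0.67. Lipid and cholesterol genes fell, with a median of -0.54 and 12 of 15 below 0 on both arrays (adjusted p = 0.00178, and adjusted p = 0.360 with an estimated correlation), among them the elongase gene Elovl1 at -1.05 ± 0.20. Oxidative phosphorylation genes fell, with a median of -0.35 and 23 of 39 below 0 on both arrays (adjusted p = 0.00365, and adjusted p = 0.360 with an estimated correlation). Cox8a had -1.10 ± 0.57, while Ndufb9 had 1.14 ± 0.05. Extracellular matrix genes fell, with a median of -0.34 and 16 of 25 below 0 on both arrays (adjusted p = 0.00337, and adjusted p = 0.489 with an estimated correlation), with the matrix protein gene Sparc at -1.02 ± 0.21. Immediate early genes fell, with a median of -0.43 and 11 of 17 below 0 on both arrays (adjusted p = 0.0138, and adjusted p = 0.360 with an estimated correlation), with the transcription factor gene Klf2 at -0.96 ± 0.16. Across all genes 31.9% were below 0 and 22.9% above 0 on both sensitized arrays, with a median of -0.06.

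Genes of allergic inflammation did not pass camera as a list in sensitized lungs. The type 2 and allergic response list had a median of -0.28 (adjusted p = 0.595), with Arg1, the arginase of alternatively activated macrophages, at -1.35 ± 0.80. Chil3 and Retnla, which such macrophages secrete, had -1.20 ± 0.31 and -0.57 ± 0.11. Inflammatory cytokines and chemokines had a median of 0.32 (adjusted p = 0.303), with Icam1, an adhesion molecule for leukocytes, at -1.39 ± 0.66 and Il1b at 0.43 ± 0.03. The medians were -0.04 for eosinophil and mast cell markers, -0.11 for neutrophil markers, 0.20 for T and NK cell markers and -0.87 for B and plasma cell markers, and none of these lists passed camera. The rotation test fry passed the T and NK cell list (adjusted p = 0.0287). Saa3 had -0.09 ± 0.35, Gclm had -0.35 ± 0.01 and the metallothionein gene Mt1 had -0.54 ± 0.06. Lcn2 had 0.04 ± 0.15 and -1.31 ± 0.89 on its 2 probes, and Mt2 had 0.61 ± 0.80 and 0.77 ± 0.26. Hmox1 had no probe with a value on all 4 arrays, and Nqo1, Cyp1a1, Cxcl5, Ccl2, Ccl11, Il13, Chia1, Muc5ac, Clca1, Scgb1a1 and Spp1 had no named probe, so they were not analysed here.

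Single genes were ranked by the smaller of their 2 array values, since none passed. Pdgfra, a growth factor receptor of lung mesenchymal cells, ranked first with 4.13 ± 0.07. It was followed by Fam220a with 3.25 ± 0.93, the RNA demethylase gene Alkbh5 with 2.74 ± 0.25, the phospholipase gene Pla2g2c with 2.67 ± 0.14 and Neurl1a with 3.45 and 2.55 on its 2 arrays. Nr1i2, a nuclear receptor that senses xenobiotics, had 3.86 ± 1.91, Utrn had 2.70 ± 0.27 and Dnajc5 had 3.25 ± 1.14. Plcb4 and Nfya had 2.45 and 2.34 on array 1 and a ratio with 0 in one channel on array 2. Of these higher genes, all but Nr1i2 had low signal or a ratio with 0 in one channel on at least 1 of the 4 arrays. Among all complete probes 26.5% did. At the lower end, Polr2e had -2.40 on array 2 and a ratio with 0 in one channel on array 1. Plin3, a lipid droplet protein, had -2.95 ± 1.05, the histone deacetylase gene Hdac3 had -2.34 ± 0.21, Fam136a had -2.21 ± 0.11 and Pxk had -3.18 ± 1.62. Hepacam had -1.99 ± 0.03, Brwd1 had -2.39 ± 0.64, Ly75, an endocytic receptor of dendritic cells, had -2.57 ± 0.91, Ing1 had -1.92 ± 0.07 and the myosin gene Myo1e had -1.99 ± 0.22. Among these lower genes, low signal or a ratio with 0 in one channel was found for Polr2e, Fam136a and Ing1.

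In the test over all 17332 probes, 0 passed an adjusted p of 0.05 in sensitized lungs, and the smallest adjusted p was 0.473. Unadjusted, 1734 probes were below 0.05, of which 805 were higher and 929 lower, where 866.6 would be expected by chance. This count and its balance depended on the processing, with 906 higher and 783 lower on centred arrays, 391 higher and 330 lower on centred and scaled arrays, and 971 higher and 660 lower with a block for the array number. The fit shared 1 residual variance between the groups, and the sensitized arrays spread more widely than the challenged arrays. Sharing can lower p-values in sensitized lungs, so the excess over 866.6 is not evidence of more responding probes. Leaving out 1 array gave 555 to 4785 probes (2723 higher and 2062 lower without sensitized array 2), and the group's own arrays alone gave 555. Of 34 lists tested, 1 rose and 12 fell, and of these 13 calls antigen presentation and extracellular matrix did not pass fry (adjusted p = 0.121 and 0.132). Without sensitized array 1 only the ribosomal, type 1, type 2 and muscle lists still passed, while the other 9 had adjusted p from 0.135 to 0.602. The club cell list also lost its call without any 1 of the other arrays, but leaving out either challenged array gives the same fit for sensitized lungs. The immediate early list lost its call without sensitized array 2, and the macrophage list lost it without low-signal probes (adjusted p = 0.071).

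**Figure D1:**
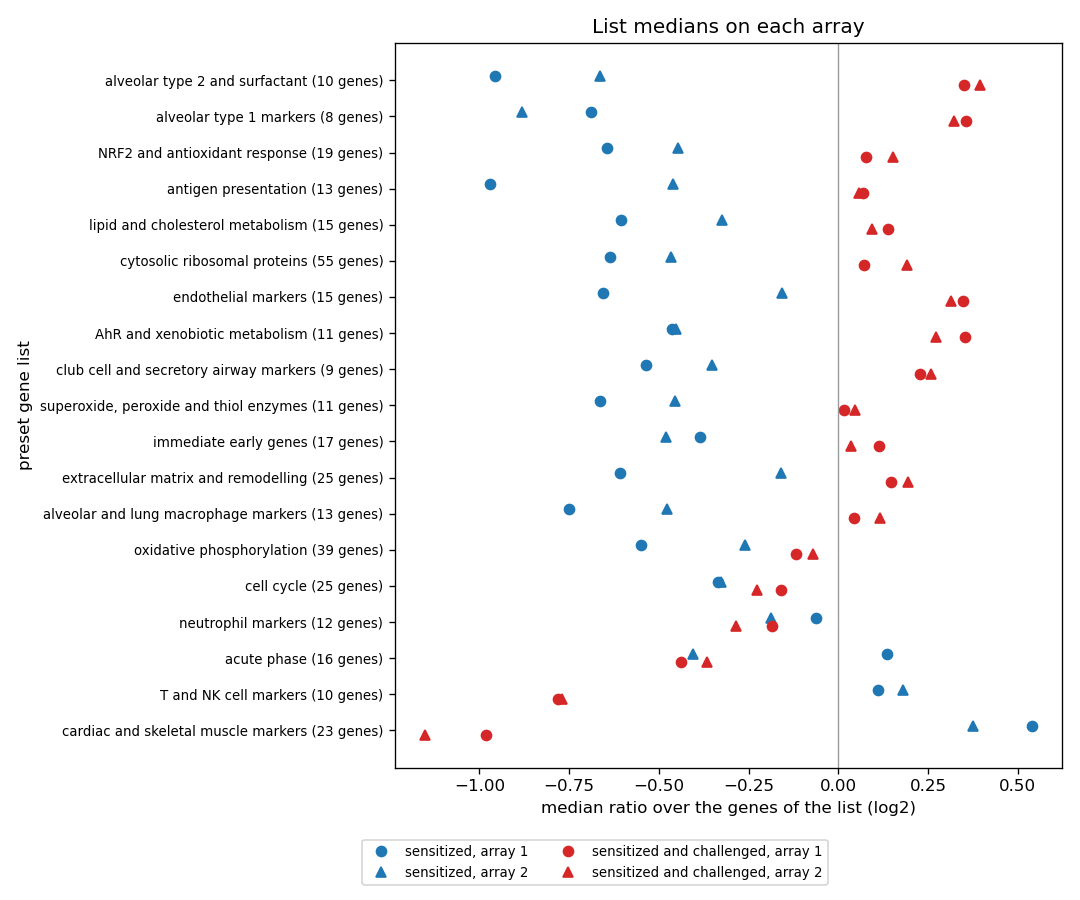
Median log2 ratio of UCP over particle-free air (horizontal axis) on each of the 4 arrays for every preset list that passed in at least 1 comparison (vertical axis, number of measured genes in brackets). The type 2 list lies at -0.96 and -0.67 on the sensitized arrays and at 0.35 and 0.40 on the challenged arrays, and the muscle list at 0.54 and 0.38 against -0.98 and -1.15.

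The second comparison asked the same of lungs that had been sensitized and challenged. Here muscle, acute phase and T cell genes were lower after UCP, and alveolar, endothelial and xenobiotic genes were slightly higher. For comparison, 25.2% of all genes were below 0 and 29.7% above 0 on both challenged arrays, with a median of 0.02. The cardiac and skeletal muscle list fell, with a median log2 ratio of -1.06, 19 of 23 genes below 0 and 0 above 0 on both arrays (adjusted p = 6.79e-23, and adjusted p = 0.494 with an estimated correlation). Myl2, the regulatory myosin light chain of the heart ventricle, had -3.06 ± 0.43. The oxygen-binding protein gene Mb had -2.29 ± 0.02, and the heart troponin genes Tnnt2 and Tnni3 had -2.28 ± 0.18 and -2.09 ± 0.19. In this list 12 genes passed when adjusted over the list alone, and 0 passed over all genes tested. The acute phase list, of genes that liver or inflamed tissue and neutrophils express, fell, with a median of -0.45 and 10 of 16 genes below 0 on both arrays (adjusted p = 1.07e-07, and adjusted p = 0.494 with an estimated correlation). Saa1 had -2.15 ± 0.09, and the fibrinogen genes Fgg and Fgb had -1.81 ± 0.20 and -1.55 ± 0.07. Adjusted over the list alone, 2 of these genes passed. Of the 10 acute phase genes below 0 on both arrays, 5 also belong to a list of liver genes, of which 28 of 31 were below 0 on both arrays, with a median of -0.94. The other 5 had means of -2.15 for Saa1, -1.37 for Orm1, -0.37 for Saa3, -0.29 for Hp and -0.03 for Timp1. Absence from the liver list does not exclude a liver source for these genes. T and NK cell markers fell, with a median of -0.62 and 7 of 10 below 0 on both arrays (adjusted p = 0.000232, and adjusted p = 0.494 with an estimated correlation). The T cell genes Cd8a, Thy1 and Cd3d had -1.68 ± 0.01, -1.05 ± 0.25 and -1.04 ± 0.32, while Nkg7 of cytotoxic cells had 0.99 ± 1.24, and 1 gene passed when adjusted over the list alone. Of the 7 T and NK cell genes below 0 on both arrays, 5 also belong to a list of thymus genes, of which 17 of 21 were below 0 on both arrays, with a median of -0.86. The other 2, Cd247 and Ccl5, had means of -0.38 and -0.39. The thymus and liver lists, and these last 2 genes, were chosen after values had been seen.

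The alveolar type 2 and surfactant list rose in challenged lungs, with a median of 0.35 and 9 of 10 genes above 0 on both arrays (adjusted p = 0.000809, and adjusted p = 0.533 with an estimated correlation). Sftpc had 0.65 ± 0.04, Lyz2, a lysozyme of type 2 cells and macrophages, had 0.66 ± 0.08 and the transcription factor gene Etv5 had 0.58 ± 0.07. Alveolar type 1 markers rose, with a median of 0.34 and all 8 above 0 on both arrays (adjusted p = 0.00381, and adjusted p = 0.494 with an estimated correlation), among them Ager at 0.42 ± 0.14 and Emp2 at 0.36 ± 0.04. The AhR and xenobiotic metabolism list rose, with a median of 0.33 and 8 of 11 above 0 on both arrays (adjusted p = 0.00130, and adjusted p = 0.494 with an estimated correlation). Its largest members were Cyp2b10 at 0.68 ± 0.03, Aox3 at 0.60 ± 0.10 and Fmo1 at 0.52 ± 0.08, all enzymes that oxidize foreign compounds. Tiparp, Aldh3a1 and Gsto1 had arrays of opposite sign, with means of -0.05, 0.01 and -0.01, and Ugt1a6a had 0.13 ± 0.08. Cyp1a1 had no named probe. AhR activity was not tested apart from the other xenobiotic enzymes of this list. Endothelial markers rose, with a median of 0.30 and 9 of 15 above 0 on both arrays (adjusted p = 0.00644, and adjusted p = 0.533 with an estimated correlation), with Eng, a receptor of vessel-lining cells, at 0.95 ± 0.10 and Vwf at 0.54 ± 0.06. Extracellular matrix genes rose, with a median of 0.16 and 13 of 25 above 0 on both arrays (adjusted p = 0.0309, and adjusted p = 0.596 with an estimated correlation), including the matrix protein gene Postn at 0.87 ± 0.37 and the metalloproteinase gene Mmp2 at 0.69 ± 0.01. In these 5 lists 0 genes passed when adjusted over the list alone.

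Neutrophil markers fell in challenged lungs, with a median of -0.30 and 5 of 12 below 0 on both arrays (adjusted p = 0.0115, and adjusted p = 0.494 with an estimated correlation). Camp and Ltf, which encode proteins of neutrophil granules, had -0.72 ± 0.33 and -0.54 ± 0.07. Oxidative phosphorylation genes fell, with a median of -0.12 and 20 of 39 below 0 on both arrays (adjusted p = 0.0309, and adjusted p = 0.533 with an estimated correlation), with Uqcrc2 at -0.38 ± 0.09. Cell cycle genes fell, with a median of -0.19 and 10 of 25 below 0 on both arrays (adjusted p = 0.0476, and adjusted p = 0.533 with an estimated correlation), and Birc5, a gene of dividing cells, had -0.75 ± 0.11. The type 2 and allergic response list had a median of 0.15 (adjusted p = 0.238), with the chemokine gene Ccl8 at 0.42 ± 0.05 and the macrophage receptor gene Mrc1 at 0.31 ± 0.03. The NRF2 list had a median of 0.16 (adjusted p = 0.183), with Srxn1 at 0.31 ± 0.00. Inflammatory cytokines and chemokines had -0.12 (adjusted p = 0.438), with Tnf at -0.58 ± 0.12 and Cxcl1 at -0.32 ± 0.06. Eosinophil and mast cell markers had a median of -0.00 (adjusted p = 0.438), with the mast cell tryptase gene Tpsb2 at -0.86 ± 0.13. Saa3 had -0.37 ± 0.00, Retnla had 0.11 ± 0.43, Gclm had 0.16 ± 0.12 and Mt1 had -0.35 ± 0.13, and the 2 probes of Mt2 had 0.15 ± 0.28 and -0.54 ± 0.47. Chil3 had 1.02 on array 2 and a ratio with 0 in one channel on array 1, as did 1 of the 2 Lcn2 probes, which had 0.30 on array 2, while the other Lcn2 probe had -0.08 ± 0.14.

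Of the single genes ranked lowest in challenged lungs, Myl2, Mb, Tnnt2 and Saa1 belong to the muscle and acute phase lists above. Prss16, a protease of the thymus, had -3.63 ± 1.66, and Satb1, which organizes chromatin in thymocytes, had -2.35 ± 0.21. Fabp1, the fatty acid binding protein of liver, had -2.38 ± 0.27. The urea transporter gene Slc14a1 had -3.49 ± 1.20, Supt20 had -2.80 ± 0.21, and Ergic2 had -2.72 on array 2 and a ratio with 0 in one channel on array 1. At the upper end were Rsrp1 with 2.56 ± 0.07, the phosphorylase kinase gene Phkg2 with 3.04 ± 0.77, the phosphatase gene Ppp6c with 2.33 ± 0.33, Otud7a with 2.09 ± 0.13 and Cpsf7 with 2.66 ± 1.02. They were followed by Akap9 with 2.36 ± 0.61, the splicing factor gene Srrm2 with 1.99 ± 0.17, Myt1 with 1.81 ± 0.02, Arid3a with 2.58 ± 1.24 and Spertl with 1.76 ± 0.13. Of these higher genes, all but Rsrp1 and Otud7a had low signal on at least 1 of the 4 arrays, and Akap9, Srrm2 and Myt1 had it on 3. Among the lowest genes, low signal or a ratio with 0 in one channel was found for Ergic2, Slc14a1, Prss16 and Saa1.

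Over all 17332 probes, 0 passed an adjusted p of 0.05 in challenged lungs. Unadjusted, 384 probes were below 0.05, of which 119 were higher and 265 lower, where 866.6 would be expected by chance, but on centred and scaled arrays 446 were higher and 743 lower. The residual variance shared with the more widely spread sensitized arrays can raise p-values here. The count is therefore not comparable with that of sensitized lungs. Leaving out 1 array gave 211 to 740 probes, with the balance turned to 330 higher and 232 lower without challenged array 2, and the group's own arrays alone gave 740. Of 34 lists, 5 rose and 6 fell, and of these 11 calls 9 did not pass fry. These were muscle, T and NK cell, acute phase, endothelial and matrix genes (adjusted p = 0.0765, 0.0765, 0.241, 0.307 and 0.504), and alveolar type 2, neutrophil, cell cycle and oxidative phosphorylation genes (adjusted p = 0.218, 0.217, 0.121 and 0.379). The AhR and alveolar type 1 lists passed fry (adjusted p = 0.0320 and 0.0498). Without challenged array 2 only the muscle, acute phase, T and NK cell and neutrophil lists still passed, while the other 7 had adjusted p from 0.217 to 0.398. Without challenged array 1 the calls of the neutrophil, matrix, cell cycle and oxidative phosphorylation lists were lost (adjusted p = 0.281, 0.051, 0.343 and 0.546), and without low-signal probes those of the neutrophil and cell cycle lists were lost (adjusted p = 0.097 and 0.125), the latter also without probes that held a ratio with 0 in one channel (adjusted p = 0.071).

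**Figure D2:**
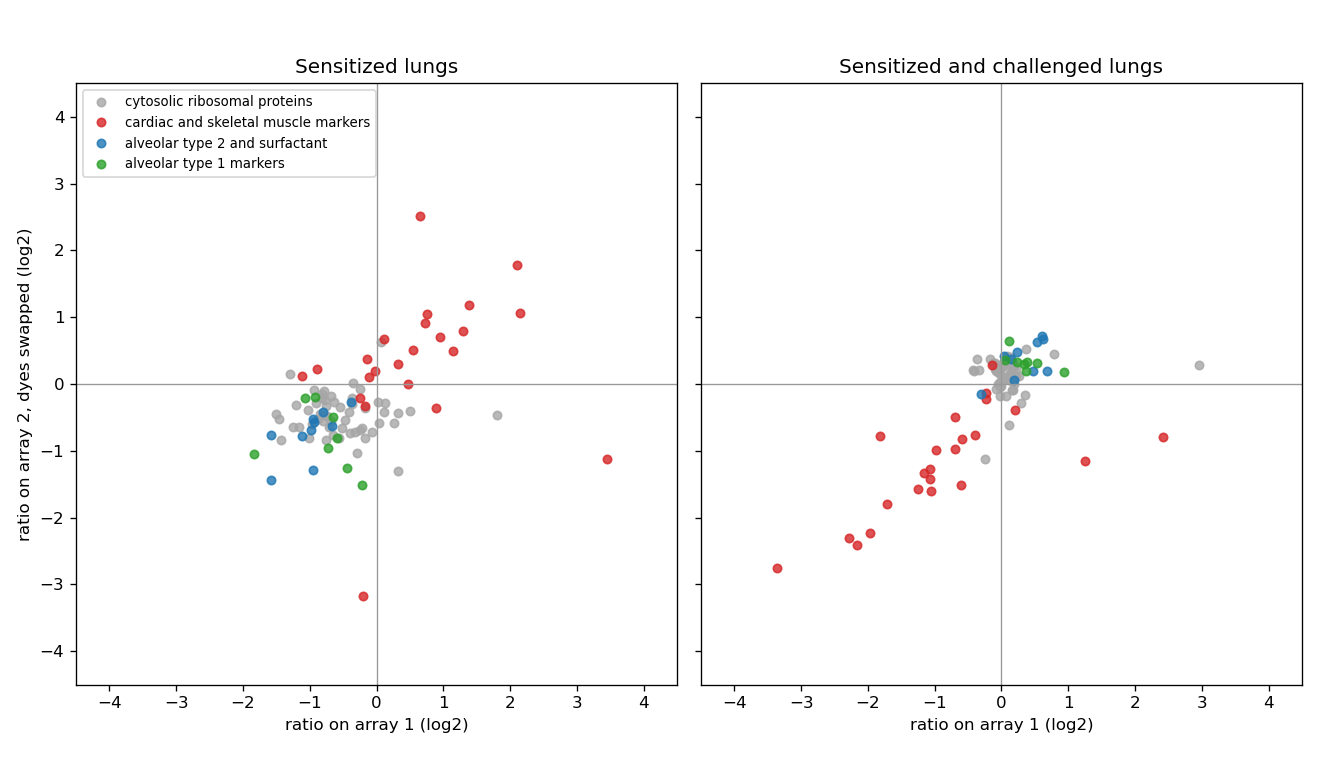
Log2 ratio of UCP over particle-free air on array 1 (horizontal axis) and on array 2 with swapped dyes (vertical axis), with 1 point per gene for the ribosomal, muscle, alveolar type 2 and alveolar type 1 lists. In challenged lungs 19 of 23 muscle genes lie below 0 on both arrays, and in sensitized lungs 12 of 23 lie above 0 on both; Rpl22 in challenged lungs (-8.30 and 0.27) lies outside the plotted range.

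The third comparison tested whether the response to UCP differed between challenged and unchallenged sensitized lungs. Most of the lists that were lower after UCP in sensitized lungs had higher ratios in challenged lungs, and the muscle and T cell lists went the other way. Each group had its own control pool, so a difference between the pools counts toward these values. Traces of neighbouring tissue were weighed as a cause for the challenged arrays only, in the closing section. In sensitized lungs the median of the muscle list lay above that of all genes by 0.531 and 0.505 on arrays 1 and 2. The thymus list lay above it by 0.219 and 0.462, and the liver list differed from it by 0.042 and -0.189. Unequal traces in either group would count toward the differences of these lists. In challenged lungs alone the ribosomal and NRF2 lists had medians of 0.10 and 0.16 and did not pass camera (adjusted p = 0.0859 and 0.183). Alveolar type 2 genes had a median difference of 1.27, with all 10 higher on both challenged arrays than on both sensitized arrays (adjusted p = 8.37e-07, and adjusted p = 0.338 with an estimated correlation). For Sftpc the difference was 1.82. Alveolar type 1 markers had a median difference of 1.12, with all 8 higher (adjusted p = 9.18e-05, and adjusted p = 0.338 with an estimated correlation). Ribosomal proteins had 0.62, with 43 of 55 higher (adjusted p = 2.53e-08, and adjusted p = 0.338 with an estimated correlation), and the NRF2 list had 0.80, with 13 of 19 higher (adjusted p = 0.00269, and adjusted p = 0.338 with an estimated correlation). The muscle list had -1.36, with 18 of 23 genes lower on both challenged arrays than on both sensitized arrays (adjusted p = 8.18e-13, and adjusted p = 0.338 with an estimated correlation), and T and NK cell markers had -1.06, with 6 of 10 lower (adjusted p = 0.00449, and adjusted p = 0.338 with an estimated correlation). The thymus list, which holds 6 of the 10 T and NK cell genes, had -1.06, and the liver list had -0.825. Both were written after values had been seen (adjusted p = 8.21e-09 and 1.81e-10 over the 2 lists, and adjusted p = 0.0684 for both with an estimated correlation). Adjusted over the list alone, 8 type 2 genes, 11 muscle genes and 1 T and NK cell gene passed, and 0 genes passed over all genes tested. Of all genes, 27.1% were higher and 17.5% lower on both challenged arrays than on both sensitized arrays, with a median difference of 0.08.

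Further lists with a higher ratio in challenged lungs were AhR and xenobiotic metabolism, with a median difference of 0.58 (adjusted p = 0.00269), lipid and cholesterol metabolism with 0.67 (adjusted p = 0.00848), club cell markers with 0.58 (adjusted p = 0.0145), immediate early genes with 0.52 (adjusted p = 0.0171) and superoxide, peroxide and thiol enzymes with 0.54 (adjusted p = 0.0171). With an estimated correlation the adjusted p = 0.338 for each of these 5. The superoxide list did not pass with a block for the array number (adjusted p = 0.051). Antigen presentation had 0.78 (adjusted p = 0.00486), endothelial markers had 0.60 (adjusted p = 0.00676) and extracellular matrix had 0.51 (adjusted p = 0.00135), and with an estimated correlation the adjusted p = 0.472 for each of these 3. The genes ranked highest for the difference were Vps35l, with a ratio with 0 in one channel on sensitized array 1, Pxk with a difference of 3.72, Syk, with a ratio with 0 in one channel on the same array, Ap1s1, an adaptor of vesicle transport, with 2.88 and Eya2 with 2.61. The lowest were Supt20 with -4.63, Slc14a1 with -5.15, Pdgfra with -3.88, Itih2, a plasma protein made by the liver, with -3.87, and Nfya with a ratio with 0 in one channel on sensitized array 2. Low signal on 1 array was also found for Slc14a1, Pdgfra, Itih2 and Nfya. In the test of the difference 0 of 17332 probes passed, with a smallest adjusted p of 0.617. Of the 14 list calls for the difference, 5 did not pass fry, namely NRF2, lipid, endothelial, matrix and antigen presentation (adjusted p = 0.0569, 0.0644, 0.105, 0.139 and 0.153). Unadjusted, 1299 were below 0.05, of which 616 were higher and 683 lower in challenged lungs, against 504 and 741 on centred arrays and 388 and 769 with a block for the array number. Leaving out 1 array gave 358 to 4201 probes, and the balance turned to 1059 higher and 842 lower without sensitized array 1, to 589 and 509 without low-signal probes and to 392 and 301 with 1 mean per gene. Without sensitized array 1 only the muscle, T and NK cell, ribosomal, AhR and both alveolar lists still passed, while the other 8 had adjusted p from 0.067 to 0.305. Without challenged array 2 the NRF2, superoxide, antigen presentation, club cell, endothelial and immediate early lists did not pass, with adjusted p from 0.068 to 0.175, the club cell list did not without challenged array 1 (adjusted p = 0.052), the immediate early list did not without sensitized array 2 or challenged array 1 (adjusted p = 0.066 and 0.083), and without low-signal probes the immediate early and lipid lists did not (adjusted p = 0.052 for both).

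The dye swap was also used without a model, by counting probes that were at least 1.5-fold from 0 on both arrays of a group. In sensitized lungs 1792 probes had the same sign on both arrays (945 higher and 847 lower) and 1581 had opposite signs, so 53.1% were concordant (95% confidence interval 51.4 to 54.8, exact binomial p = 0.000298). In challenged lungs 620 had the same sign (221 higher and 399 lower) and 482 had opposite signs, so 56.3% were concordant (95% confidence interval 53.3 to 59.2, exact binomial p = 3.60e-05). The balance of higher and lower probes in sensitized lungs was 1058 to 726 on centred arrays and 554 to 673 without low-signal probes. At 2-fold, 46.9% were concordant in sensitized lungs (exact binomial p = 0.0632) and 60.7% in challenged lungs (exact binomial p = 0.000325). From the number of higher and lower probes on each array alone, 48.7% and 50.4% would be concordant at 1.5-fold in sensitized and challenged lungs, and 48.6% and 52.7% at 2-fold. Probes are not independent of each other, so these p-values describe the arrays alone.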

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

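The tests of explanations in this part, and the thymus and liver gene lists they use, were chosen after the results had been seen, while the tests of the 34 preset lists were planned.

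What drew attention to the following results was a difference between the 2 groups of mice in the median ratio of a whole gene list. The median log2 ratio of challenged minus sensitized lungs was 1.27 for alveolar type 2 genes, 1.12 for alveolar type 1 markers, 0.62 for ribosomal proteins and 0.80 for the NRF2 list. It was 0.78 for antigen presentation, 0.67 for lipid and cholesterol metabolism, 0.60 for endothelial markers, 0.58 for AhR and xenobiotic metabolism and 0.577 for club cell markers. It was 0.535 for superoxide, peroxide and thiol enzymes, 0.515 for immediate early genes and 0.514 for extracellular matrix. Muscle markers had -1.36 and T and NK cell markers had -1.06.

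Genes of heart, thymus and liver lay low together in challenged lungs: 19 of 23 muscle genes (82.6%), 17 of 21 thymus genes (81.0%) and 28 of 31 liver genes (90.3%) were below 0 on both arrays, with medians of -1.06, -0.86 and -0.94. The tables argue against a dye effect, since over these genes the median size of the mean of the 2 swapped arrays was 7.39 times that of 50% of their difference, and against low signal, since low-signal spots had medians of -0.014 and -0.005 on the same arrays. Some of these genes had been seen low on both arrays, which raises the 7.39. Without genes named by the ranking or held by a preset list, the 2 median sizes were 0.49 and 0.16 for thymus genes. They were 0.77 and 0.12 for liver genes so reduced, and 1.06 and 0.14 for the muscle list, which was written in advance. Traces of neighbouring tissue, carried along in unequal amounts in the UCP and the control samples, may account for the pattern, and 10 of 13 thymus genes (76.9%) and 21 of 24 liver genes (87.5%) held it when genes named by the ranking or held by a preset list were left out. Some abundant genes moved less than such traces would need, with Alb at -0.04 and -0.74, Actc1 at 1.26 and -1.15 and Ckm at 0.21 and -0.39, while Apoa2 had -1.75 and -1.77. A lower expression of these genes in the lung itself after UCP, including in the heart-type muscle around mouse pulmonary veins, was not tested and stays open.

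Lists of widely expressed and alveolar genes fell together in sensitized lungs, and a bias of the ratio with signal that 1 scaling factor per array would leave is one candidate explanation. Low-signal spots lay above the others by 0.198 on array 1 and 0.367 on array 2, which cannot decide. The 1347 probes that were missing on a challenged array, and so are likely dim, lay above the others by 0.342 and 0.551. This goes with higher ratios for dim probes but does not show that they set the baseline. The array medians were 0.122 and -0.067 over all values, and 0.0975 and -0.092 over probes with values on all other arrays. These 1347 probes were also not among the probes on which the lists were tested. The tables argue against low-signal spots alone, since 91.7% of the lists that fell did so again without low-signal probes. An effect of UCP on alveolar cells of sensitized mice was not tested apart from this bias and stays open.

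Arrays of different groups and opposite dye orientation ran against each other, with rank correlations of -0.30 for sensitized array 1 with challenged array 2 and -0.14 for sensitized array 2 with challenged array 1. A dye effect shared by the probes would separate pairs by orientation, and the part of the correlation that follows orientation was 0.101, which cannot decide. Opposite effects of UCP in the 2 groups would also make the cross-group pairs of the same orientation negative, but these had 0.0156 for array 1 and -0.0562 for array 2. A shared dye effect would raise both, so this cannot decide either, and both explanations stay open.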

How the results depend on the processing

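The settings without stored ratios of 0, without low-signal probes and with the lists on scaled arrays were chosen after the data had been seen. In each comparison 0 probes passed under every setting but those named here. With array 2 turned, 1 probe passed in sensitized lungs and 1 for the difference, an unnamed probe with a stored ratio of 0 on both sensitized arrays. Leaving out arrays in turn gave 0 to 57 probes in sensitized lungs, 0 to 86 in challenged lungs and 0 to 79 for the difference. Of the probes that passed without an array 2, 56 of 57, 82 of 86 and 75 of 79 held a stored ratio of 0 on an array left in the fit, which shows where most of these calls came from. Each of these fits leaves 1 array in a group, so its spread comes from the other group alone, and the counts do not measure how that array's group varies. For the group that keeps both arrays, such a fit equals fitting its own arrays alone, so their equal counts are 1 result.

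The array numbers stand for dye orientation and do not pair samples. With a block for the number, 0 probes passed in each comparison, and the lists passing were 13, 12 and 13 against 13, 11 and 14 in the fit without the block. The only call lost under the block was that of the superoxide list for the difference (adjusted p = 0.051). Deviations of same-numbered arrays correlated by rank at 0.230.

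All 38 list calls kept their direction in the 10 settings in which lists were tested, but over these settings 86 list results lost the call and 294 kept it. Some settings could hardly change the direction. The block, the estimated correlation and leaving out an array of the other group all leave a group's mean as it was. Lists were not tested with array 2 turned, with missing values kept or with each group fitted alone. With an estimated correlation 0 lists passed in sensitized lungs, 0 in challenged lungs and 0 for the difference, a form in which 0 of 10 simulated lists with a shift of 0.5 passed. Larger shifts and correlated genes were not simulated, so the simulation does not say why lists with larger medians did not pass. Leaving out arrays gave 4 to 12 lists in sensitized lungs, 4 to 11 in challenged lungs and 6 to 14 for the difference. Centring left 13, 11 and 14, scaled arrays 14, 11 and 15, no stored ratios of 0 13, 10 and 14, and no low-signal probes 15, 10 and 13.

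Concordance in sensitized lungs went to the other side of 50% at 2-fold (46.9%, where the array margins give 48.6%), and the cause was not tested. At the smaller alternative size it was 56.5% in sensitized and 55.9% in challenged lungs. With array 2 turned it was 46.9% in sensitized and 43.7% in challenged lungs, which follows from the turn. Some genes of the fixed names had arrays of opposite sign, so leaving out arrays gave -0.34 to 0.16 for Saa3 and -0.067 to 0.15 for Lcn2 probe 1756 in sensitized lungs. In challenged lungs it gave -0.17 to 0.02 for Lcn2 probe 1756, -16.82 to 1.02 for Chil3, -16.82 to 0.30 for Lcn2 probe 4436, -0.20 to 0.41 for Retnla and -0.05 to 0.35 for Mt2 probe 11896. The cause was not tested beyond the stored ratios of 0. Low-signal spots made up 13.02% and 8.38% of the sensitized arrays and 7.04% and 6.61% of the challenged arrays.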

Other observations

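Several gene groups outside the lists that camera called are given here with single members, of which only some had close values on both arrays of a group. Hpgds, which makes prostaglandin D2 in mast cells and T helper cells, had a mean log2 ratio of 1.37 ± 0.10 (SD, n = 2 arrays) in sensitized lungs and -1.81 ± 1.82 in challenged lungs, within an arachidonate and leukotriene list whose medians were -0.02 and -0.10. B and plasma cell markers had a median of -0.87 in sensitized lungs (adjusted p = 0.0779) and 0.23 in challenged lungs (adjusted p = 0.438), with Cd79b of the B cell receptor at -1.09 ± 0.49 and 0.26 ± 0.34. Hypoxia and glycolysis genes had a median of -0.33 in sensitized lungs (adjusted p = 0.0628), with Pkm at -0.77 ± 0.18 and Pgam1 at -0.72 ± 0.10, and 0.12 in challenged lungs (adjusted p = 0.426). Heat shock and unfolded protein genes had -0.22 (adjusted p = 0.0628) and 0.08 (adjusted p = 0.273), with the chaperone gene Hsp90b1 at -0.63 ± 0.18 and 0.26 ± 0.05. Interferon response genes had medians of -0.07 and 0.07, ciliated cell markers 0.06 and -0.10, and smooth muscle markers -0.22 and 0.06, and none of these passed camera, while fry passed the smooth muscle and heat shock lists in sensitized lungs (adjusted p = 0.0283 and 0.0287) and again for the difference (adjusted p = 0.0416 for both). In sensitized lungs the AhR, cell cycle and fat tissue lists had medians of -0.40, -0.37 and -0.23. They passed fry (adjusted p = 0.0283 for each) but not camera (adjusted p = 0.0540, 0.124 and 0.173). For the difference fry also passed the macrophage and fat tissue lists (adjusted p = 0.0416 and 0.0456), which camera did not.

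Thymus genes rose in sensitized lungs, with a median of 0.20 (adjusted p = 0.0216, 0.0348 with a block for the array number, and adjusted p = 0.3002 with an estimated correlation), and liver genes had -0.14 (adjusted p = 0.777). In challenged lungs both lists fell (adjusted p = 3.64e-15 for thymus and 2.78e-28 for liver, and adjusted p = 0.0249 for both with an estimated correlation). These values were adjusted over the 2 lists only, and the lists were written after several members had been seen.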
